A study of Mus musculus with 6 samples.

How the data were processed

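Single-colour scanner output of 6 arrays was analysed, 3 hybridized with cortex RNA and 3 with thymus RNA; groups and replicate numbers came from the sample titles. Per the labels, RNA pools of 6 cortices and 5 thymi were labelled with Cy5 by reverse transcription from random hexamers, with 15 µg per array. The values used were spot intensities as deposited, on the scanner's linear 16-bit scale with no normalization: per the file headers the software segmented spots automatically and reported a local background beside the median, mean and SD of each. The scanner's flag column, another deposited value, marks spots as bad. The name of the quantification software is not given in the sources used here, and the number of arrays limits the precision.

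The deposited value table of the series covers 20 probes, in intensity units that the authors scaled. Set against the scanner values, 5 of its 6 columns equalled signal median minus background median, averaged over unflagged spots and multiplied by 1 factor per array, within 1% at every probe with a value. The factors were 1.00 and 1.30 for cortex 1 and 2 and 1.85, 3.41 and 3.39 for thymus 1 to 3. The column of cortex 3 instead equalled 5.68 times the scanner values of thymus 1. Column medians were 932, 1138 and 1918 for cortex and 625, 317 and 750 for thymus. The scale is thus linear, uncentred and not a ratio, and how the factors were chosen stays unknown. The table served as an alternative only.

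Foreground medians were corrected with backgroundCorrect (normexp, offset 50) of limma 3.58.1 in R 4.3.3, fitted on all spots. Flagged and control spots were then left out, spots of a probe were averaged on the log2 scale, and arrays were quantile-normalized. A spot was above background where its median exceeded the local background median by 2 SD of the background, and a probe where most of its unflagged spots did. Probes above background on at least 3 of 6 arrays, with at least 2 values per tissue, were fitted with lmFit and eBayes, cortex minus thymus, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 590 probes, 465 were tested. Different oligos of a gene were kept apart.

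Gene symbols came from the RefSeq gene table of GRCm38.p6, used for names only. The accession matched for 206 probes, 309 were named from the class and name printed in the files, and 75 kept the printed name. Where name and accession disagreed, as for a Gad2 oligo printed as GAD67, the accession was used. Of the probes, 20 were printed as rat sequences. No genome or oligo sequence was used here, so no positions are given.

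Of 31 gene lists, 23 had a probe on the array, 20 had at least 3 tested probes and 3 had 2 (astrocyte and oligodendrocyte markers and transmitter transport). The 8 lists with no probe were glycine and histamine receptors, synaptic vesicle release, postsynaptic scaffold, and markers of thymocytes, thymic epithelium with B and myeloid cells, dividing cells, and microglia with vessel and blood cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. The count of probes above background per array was compared with a two-sided exact permutation test. Groups, main tests, lists, the rule for named genes and the alternatives not said to be chosen later were fixed before the data were examined. The rule took the 15 largest differences in each direction among probes past the threshold, above background on all 3 arrays of the brighter tissue and without overlap between tissues, the 3 smallest p-values of each list, and all tested marker and housekeeping probes; any gene named outside it is said to be so. Some genes that the rule took are not reported here.

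The headers gave 3 scan settings: setting 1 held cortex 1, cortex 2 and thymus 1, setting 2, with a coarser pixel grid, held cortex 3 and thymus 2, and setting 3 held thymus 3 alone. Scan days were shared by cortex 1 and thymus 1 only. Alternatives covered background correction, offset, scaling, filter, spot summary, flags, blocks for replicate number and scan setting, each array left out in turn, other limma settings, a minimum fold and the value table. The fit was tested on simulated data: over 20 simulations with 200 changed probes among 465, split evenly between the tissues, 43.6% of 2-fold and 88.4% of 4-fold changes were called, and 5.78% of calls were unchanged probes. Where all 200 simulated changes were higher in cortex, a mean of 42.6 unchanged probes were called higher in thymus. A simulated list shifted by 1 log2 unit passed camera in 20 of 20 simulations, and in 19 with an estimated correlation. Probes were simulated as independent of each other there. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures.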

Results

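Cortex and thymus of B10D2 mice were compared on a spotted oligonucleotide array for genes of neurotransmission, most of them represented by 2 oligonucleotides (oligos). One RNA pool was made per tissue, from 6 cortices and from 5 thymi. Of each pool, 15 µg was labelled with Cy5 for each of 3 hybridizations. Each array held 1568 spots, of which 1192 were gene spots, 320 were blank or buffer spots and the rest were controls. The gene spots made up 590 probes of 288 sequence entries. The 3 arrays of a tissue are hybridizations of 1 pool, so the limma p-values of single probes measure the spread between hybridizations. No p-value given here measures the spread between animals. The title of the series names hybridization kinetics on the chip and the optimization of expression experiments as its subject; the labels name no question for the tissue contrast.

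More of the gene probes on the array gave signal with cortex RNA than with thymus RNA. On the cortex arrays 509, 478 and 419 of the 590 probes lay above background, a mean of 468.7 ± 45.7 (SD, n = 3). On the thymus arrays 393, 270 and 282 probes did, a mean of 315.0 ± 67.8 (SD, n = 3). The lowest cortex array was above the highest thymus array, and the difference of 154 probes had p = 0.1 in the two-sided exact permutation test, the smallest p that 3 arrays against 3 can give. Cortex was also above thymus within each scan setting that held both tissues: 509 and 478 against 393 in setting 1, and 419 against 270 in setting 2. The median net signal of gene spots, signal minus local background, was 2542, 1763 and 830 on the cortex arrays. It was 956, 480 and 599 on the thymus arrays. Control spots printed as G3PDH had median signals of 65535 (the scanner's ceiling), 64886.5 and 24543 on the cortex arrays. On the thymus arrays these were 25739.5, 11074.5 and 10767.2. By both measures cortex was brighter within each scan setting that held both tissues, but cortex 3 was dimmer than thymus 1. The counts of probes above background were not adjusted for array brightness. They therefore cannot tell brighter arrays from more genes expressed. Of the blank spots, with flagged ones included, 5.62% to 10.3% were above background. Among unflagged blank spots 5 of 126, 6 of 123 and 4 of 126 were on the cortex arrays. On the thymus arrays 8 of 126, 8 of 123 and 8 of 120 were.

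Replicate arrays resembled each other more than they resembled the other tissue. After scaling, Pearson's r across probes, which are not independent replicates, was 0.916 to 0.950 between cortex arrays, with a mean of 0.933. Between thymus arrays it was 0.801 to 0.874, with a mean of 0.846. Between arrays of different tissues it was 0.583 to 0.687. The median SD of a tested probe over 3 arrays was 0.33 log2 units in cortex and 0.44 in thymus.

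Among probes above background on at least 1 thymus array, the largest differences toward cortex lay at genes of a neuronal enzyme, a myelin protein, a glutamate receptor and a kinase. Eno2, the neuronal form of enolase, was higher by 4.34 ± 0.57 log2 units (SE, n = 3 arrays per tissue) on one oligo and by 2.22 ± 0.35 on the other (adjusted p = 1.42e-05 and 9.36e-05, limma). Gria2, an AMPA receptor subunit, was higher by 3.66 ± 0.48 and 3.17 ± 0.55. One oligo of Mbp, which encodes a myelin protein, was higher by 3.66 ± 0.41, with values on 2 thymus arrays only. Both oligos of a kinase printed as ca/cal kin2 were higher, by 3.63 ± 0.38 and 3.33 ± 0.41. The Mbp oligo and the second kinase oligo were saturated on 2 of 3 cortex arrays. On the thymus arrays, the more changed oligos of Eno2 and Gria2, the Mbp oligo and the first kinase oligo were above background on 2 arrays, and the other Gria2 oligo on 1.

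Several further cortex-higher probes were above background on no thymus array, so only a lower bound of their ratio can be given. Each bound sets the cortex mean against the higher of the probe's own thymus value and the lowest value of any probe above background on that array. The second oligo of Cck, the neuropeptide cholecystokinin, was at least 9.09-fold higher in cortex (adjusted p = 1.67e-06). One oligo of Gad2, an enzyme of GABA synthesis, was at least 5.55-fold higher, and Grin2a, an NMDA receptor subunit, at least 4.19-fold. The bounds were 3.71-fold for the potassium channel gene Kcnd2, 2.91-fold for the pacemaker channel gene Hcn2 and 4.67-fold for Kcnt1, whose oligo was designed on a rat sequence. They were 4.0-fold for Adcyap1r1, the receptor of the peptide PACAP, 2.88-fold for the serotonin receptor gene Htr2c, and 2.69-fold and 2.74-fold for the oligos of the GABA-A receptor gene Gabra4. The other oligo of Htr2c did not pass, at -0.74 ± 0.35 (adjusted p = 0.0972). That of Kcnt1, above background on 2 of 6 arrays, was not tested.

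The largest differences toward thymus under quantile scaling were taken among probes above background on all 3 thymus arrays. They lay at probes of epithelial sodium channel subunits, ribosomal proteins, a β-adrenergic receptor, transcription factors and potassium channels. Of all 110 thymus-higher calls, 0 were kept without scaling and 35 with arrays centred on the control genes. Scnn1b and Scnn1a, subunits of the epithelial sodium channel, differed by -2.70 ± 0.34 and -2.18 ± 0.36 log2 units, cortex minus thymus (SE, n = 3 arrays per tissue; adjusted p = 9.29e-06 and 0.000121, limma). Both oligos of a further subunit, Scnn1g, did not pass, at -0.12 ± 0.36 and 0.09 ± 0.40. Rpsa and Rps4x, which encode ribosomal proteins, differed by -2.48 ± 0.34 and -2.44 ± 0.38 on their most changed oligos. The β-adrenergic receptor gene Adrb3 differed by -2.35 ± 0.45. The transcription factor genes Otx1 and Pax5, the latter a regulator of the B cell lineage, differed by -2.47 ± 0.46, with values on 2 cortex arrays only, and -2.33 ± 0.35. The other Pax5 oligo did not pass, at -0.30 ± 0.37. Among potassium channel genes, Kcne3 differed by -2.50 ± 0.42, Kcna3, the main voltage-gated potassium channel of T lymphocytes, by -2.01 ± 0.39, and Kcna7 by -2.02 ± 0.37. Kcnj14 and the probe printed as rsk4.rat differed by -1.94 ± 0.38 and -1.94 ± 0.34, and the GABA receptor gene Gabrr2 by -2.15 ± 0.39. The entries named Kcnj1 went both ways: an oligo of one differed by -2.11 ± 0.38, an oligo of another, on a rat sequence, by 2.88 ± 0.40 (adjusted p = 2.19e-05), and both of a further rat entry did not pass, at -0.64 ± 0.39 and 0.66 ± 0.35. On the cortex arrays the Otx1 and Pax5 probes were above background on 1 of 3, and those of Scnn1b, Scnn1a, Adrb3, Kcne3, Gabrr2 and the thymus-higher Kcnj1 oligo on 2 of 3.

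**Figure D1:**
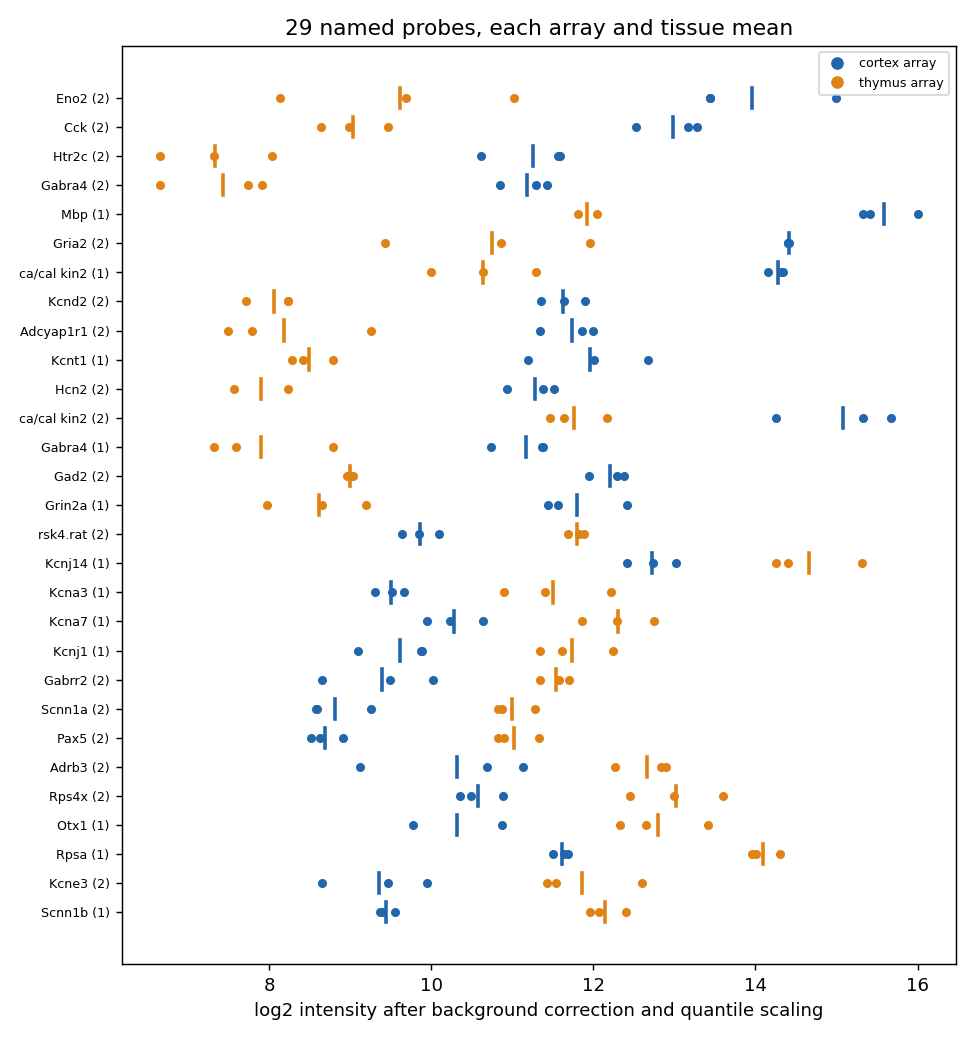
Log2 intensity after background correction and quantile scaling (x axis) of 29 named probes (y axis, gene with oligo number), with a point per array and a bar at each tissue mean. The upper 15 probes are higher on every cortex array and the lower 14 on every thymus array.

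Of 465 tested probes, 223 had an adjusted p under 0.05 in limma, 113 higher in cortex and 110 higher in thymus. They came from 158 of 251 tested genes, and 204 of them differed at least 2-fold. The arrays of the tissues did not overlap at 259 tested probes, or 55.7%, where chance gives 10%. Of the 113 probes higher in cortex, 48 were above background on no thymus array. With scan setting as a block the count was 219 (111 and 108). Within setting 1, 222 of 222 called probes with values kept their sign, within setting 2, 220 of 222, and between the cortex and thymus arrays scanned on 1 day, 220 of 220; these probes were called on the same arrays, so their signs there were largely set by that choice. The balance of directions followed the scaling: it was 133 to 36 with arrays centred on the control genes and 117 to 0 without scaling, where the median log2 difference of tested probes was 0.37 and 0.86 in place of -0.10. The control class itself held 12 of 50 tested probes higher in thymus and 3 in cortex under quantile scaling, with a median of -0.28. Centring on it is thus no independent check. Without scaling 6 probes were higher in thymus at an unadjusted p under 0.05 in limma. Leaving out cortex array 1, 2 or 3 left 117, 111 or 139 calls, among 355, 363 or 385 tested probes. The filter stayed at 3 arrays there, so probes above background on no thymus array were not tested.

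**Figure D2:**
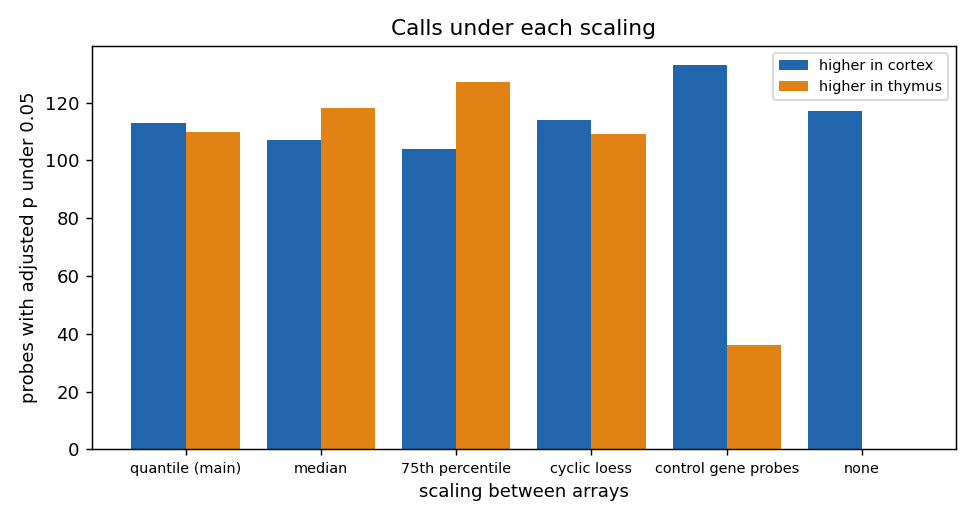
Number of probes with an adjusted p under 0.05 (y axis) higher in cortex and higher in thymus under each scaling between arrays (x axis). Quantile scaling gave 113 and 110, centring on control gene probes 133 and 36, and no scaling 117 and 0.

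Ionotropic glutamate receptor genes were higher in cortex as a list in camera at the preset correlation. Their 27 tested probes came from 13 genes, and oligos of a gene counted as separate members. Of these probes, 16 were higher in cortex, none was higher in thymus and 11 did not pass. Adjusted over the list alone, 17 were higher. Besides Gria2 and Grin2a, a kainate receptor oligo of Grik2 was at least 1.83-fold higher, while the other 3 Grik2 oligos did not pass, at -0.11 to 0.34. The median difference was 1.34 log2 units, or 0.87 with 6 probes at their bounds, and the list passed camera (adjusted p = 0.000188). With an estimated correlation the list did not pass (adjusted p = 0.150). Its median was 1.39 within scan setting 1, 1.19 within setting 2, 1.39 on the shared scan day, and 1.2 with scan setting as a block. It was 2.36 without scaling and 1.86 centred on control genes, where the median of all tested probes was 0.86 and 0.37. Without the 2 arrays of coarse pixel grid, a choice made after seeing the data, the list median was 0.78 (adjusted p = 0.000748). Without cortex array 1, 2 or 3 it was 0.67, 0.75 or 0.88, and the list passed each time (adjusted p = 0.00288, 0.000295 and 0.000269). In these fits with 2 cortex arrays the filter stayed at 3 arrays, so probes above background on no thymus array were not tested. Over probes above background on all 6 arrays the list median was 0.998 and the list did not pass (adjusted p = 0.0613). However, that filter removes every probe dim in thymus, among them 48 of the cortex-higher calls, and moves the median of tested probes to -0.52.

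The neuron marker list held the 6 probes of Eno2 and Gad2. Of these, 5 were higher in cortex, also adjusted over the list alone, with a median of 1.86 log2 units, or 1.70 with 2 probes at their bounds (camera adjusted p = 0.0141). With an estimated correlation it did not pass (adjusted p = 0.348). The probe that did not pass was a Gad2 oligo printed as GAD67, at 0.12 ± 0.38. The median was 2.28 in scan setting 1, 2.05 in setting 2, 2.24 on the shared scan day and 2.02 with scan setting as a block. The list lost its call without thymus array 1 (adjusted p = 0.0692) and without the coarse-grid arrays (adjusted p = 0.0816), with medians of 2.05 and 2.22, not below that over all arrays.

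The remaining lists did not pass camera, and several held members of both directions. Of 27 GABA receptor probes, 9 were higher in cortex and 3 in thymus, with Gabra4 among the former and Gabrr2 among the latter. Of 102 potassium channel probes, 30 were higher in cortex, 24 in thymus and 48 did not pass. These balances depend on the scaling: with arrays centred on the control genes 37 potassium channel probes were higher in cortex and 9 in thymus, and 9 and 2 GABA receptor probes. Without scaling the counts were 31 and 0, and 9 and 0, in limma, with 1 potassium channel probe and no GABA receptor probe higher in thymus at an unadjusted p under 0.05. Metabotropic glutamate receptors had 3 of 9 probes higher in cortex and none in thymus, and calcium channels 2 of 6 and none. Among the metabotropic members were Grm7 and Grm3, at least 1.48-fold and 1.65-fold higher. In transmitter synthesis and breakdown 5 of 12 probes were higher in cortex and 1 in thymus. The gene Nos1 was higher in cortex on both oligos of one sequence entry, at least 1.28-fold on the first and by 1.39 log2 units on the second. Of another sequence entry, one oligo differed by -1.91 ± 0.38, above background on 2 of 3 thymus arrays, and the other did not pass, at -0.57. Counts adjusted over the list alone were the same as these except for calcium channels, with 1.

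Receptor lists for monoamines, purines and opioids each held more probes called higher in thymus than in cortex under quantile scaling, and none of them passed camera. Adrenergic receptors had 5 of 11 probes higher in thymus and none in cortex, with a median of -0.91 log2 units (camera adjusted p = 0.0501); adjusted over the list alone, 6 were higher in thymus. Serotonin receptors had 9 of 19 higher in thymus, among them an oligo of Htr3b at -2.18 ± 0.35 and one of Htr6 at -1.51 ± 0.35, both above background on 2 of 3 thymus arrays, and 1, Htr2c, in cortex (median -0.74, camera adjusted p = 0.0501). The other Htr3b oligo did not pass, at -0.17 ± 0.43. Purine receptors had 6 of 9 higher in thymus, with both Adora3 oligos at -1.87 ± 0.37 and -1.69 ± 0.37 though above background on only 1 and 2 of 3 thymus arrays and on 2 and 1 of 3 cortex arrays (median -0.998, camera adjusted p = 0.163). Dopamine receptors had 4 of 9 higher in thymus, among them a Drd3 oligo at -1.64 ± 0.35 that was above background on 1 of 3 thymus and 2 of 3 cortex arrays, and 1 in cortex, an oligo of Drd2 at least 1.17-fold higher. The 5 opioid and cannabinoid probes had 3 higher in thymus, among them Oprm1 at -1.52 ± 0.37, and 1 in cortex, the cannabinoid receptor gene Cnr1, at least 2.23-fold higher. These thymus-higher counts depend on the scaling: in the order given they were 2, 2, 2, 1 and 0 with arrays centred on the control genes, and 0 in each list in limma without scaling. At an unadjusted p under 0.05 in limma, 1 adrenergic probe and no probe of the other 4 lists was higher in thymus without scaling, and 1 opioid probe with arrays centred on the control genes. Without scaling the adrenergic, serotonin and dopamine medians turned to 0.11, 0.10 and 0.22, and the purine and opioid medians were -0.14 and -0.06 in place of -0.998 and -1.08. The median of all tested probes was 0.86 without scaling, so these list medians stayed below it. The camera adjusted p was then 0.0614 for adrenergic and 0.0965 for serotonin receptors. Adjusted over the list alone, the serotonin, purine, dopamine and opioid counts were the same.

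Peptides, growth factors and signalling genes were mixed under quantile scaling. Of 14 neuropeptide probes, 5 were higher in cortex and 4 in thymus; the tachykinin receptors counted here and under receptors. Both oligos of Cck were higher in cortex, as was Cort, at least 2.06-fold. Of 18 neuropeptide receptor probes 4 were higher in cortex and 6 in thymus, the latter with Vipr2 at -1.85 ± 0.37 and Sstr3 at -1.57 ± 0.34. Of 9 neurotrophin probes 3 were higher in cortex, both oligos of the neurotrophin receptor gene Ntrk2 at 2.98 ± 0.38 and 2.28 ± 0.38 and one of Ntrk3 at 2.55 ± 0.38, and 3 were higher in thymus. Acetylcholine receptors had 2 of 18 probes higher in cortex and 4 in thymus, and G protein and cyclase signalling 2 and 2 of 8. The sodium channel list, of Scn4a and epithelial subunits only, had none and 2 of 5. The wider sodium channel class printed in the files, looked at after the data were seen, had 4 of 13 higher in cortex and 2 in thymus. Cytokines had none and 1 of 4, an oligo of Tgfb1 at -2.04 ± 0.51, above background on 2 of 3 thymus arrays. Adjusted over the list alone, acetylcholine receptors had 3 higher in thymus, and the counts of these other lists were the same. With arrays centred on the control genes, 5 neuropeptide probes were higher in cortex and 1 in thymus, 5 and 2 neuropeptide receptor probes, 3 and 0 neurotrophin probes, 2 and 1 acetylcholine receptor probes and 3 and 0 signalling probes; 1 neurotrophin probe and no signalling probe was higher in thymus at an unadjusted p under 0.05 in limma. Without scaling no probe of the lists in this paragraph was called higher in thymus in limma, and 1, of a sodium channel, was at an unadjusted p under 0.05.

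Markers of other cell types were few. The 2 oligos of Mbp, the only tested oligodendrocyte marker, passed in opposite directions, at 3.66 ± 0.41 and -1.44 ± 0.36, the former saturated on 2 of 3 cortex arrays; the latter did not pass without scaling or with arrays centred on the control genes. The astrocyte marker Slc1a3, a glutamate transporter and the only tested member of the transporter list, was higher in cortex by 1.76 ± 0.39 on one oligo and did not pass on the other. No probe belonged to the lists for thymocytes, thymic epithelium, dividing cells or microglia, vessel and blood cells. Of 19 housekeeping probes, 1 was higher in cortex, an α-tubulin oligo at 1.37 ± 0.41 that was saturated on 1 of 3 cortex arrays. Another 6 were higher in thymus, each an oligo of Rpsa, Rps4x or Rpl3. With arrays centred on the control genes 3 were, and without scaling 0 in limma, or 2 at an unadjusted p under 0.05. An Rps4x oligo at 0.46 ± 0.85 and Rpl3 oligos at 0.37 ± 0.35 and -0.76 ± 0.34 did not pass. The list median was -0.56 (camera adjusted p = 0.221) and 0.19 without scaling. The probes of Gapdh, Hprt and Actb did not pass, with differences from -0.92 ± 0.40 to 0.30 ± 0.38. One Gapdh oligo was saturated on all 3 cortex arrays.

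**Figure D3:**
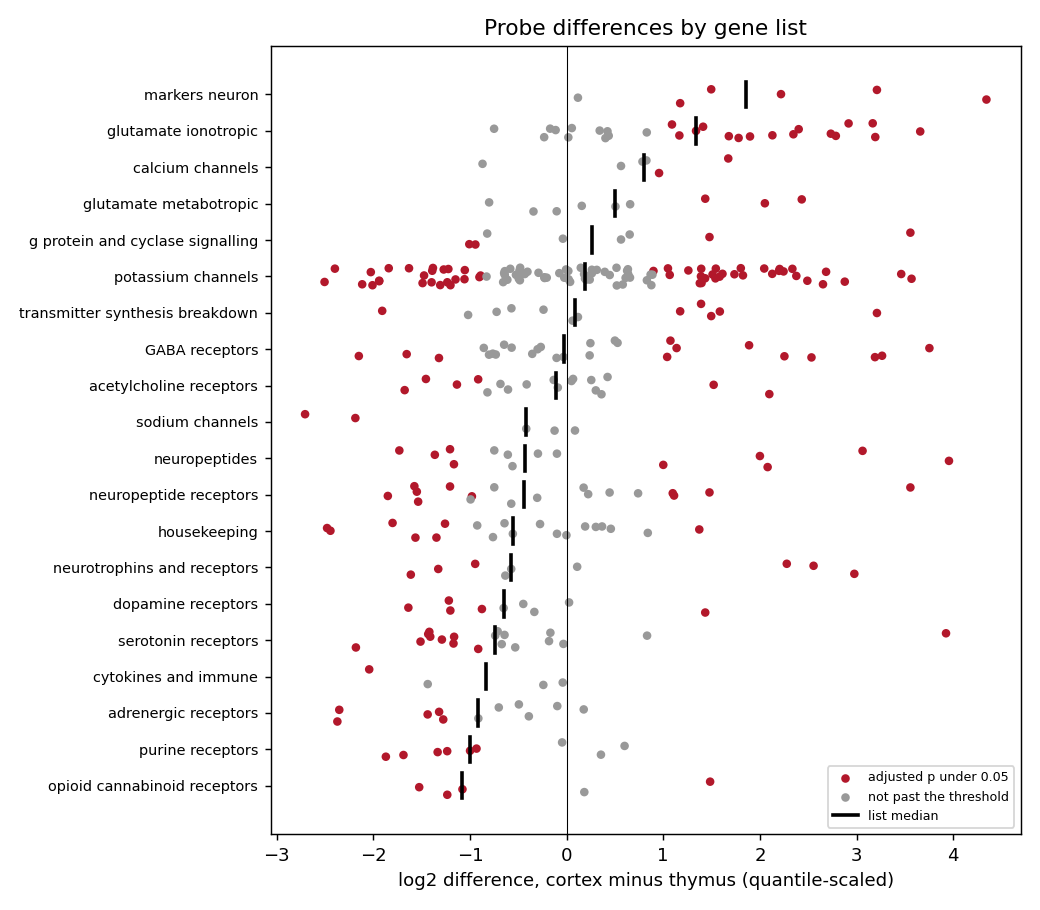
Log2 difference, cortex minus thymus (x axis), of each tested probe in the 20 lists with at least 3 tested probes (y axis), with black bars at list medians and red points for an adjusted p under 0.05. The neuron marker and ionotropic glutamate medians, 1.86 and 1.34, lie farthest to the right; the scaling sets where 0 lies.

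The 2 oligos of a gene mostly moved together. Over 173 sequence entries with both oligos tested, the differences had the same sign in 122, or 70.5%. Pearson's r across entries was 0.540 and Spearman's rho 0.520 (each p = 1e-05, the smallest that 100000 permutations can give); entries are not independent replicates. Both oligos passed at 55 entries, in the same direction at 48 and in opposite directions at 7, among them Prlr, Kcna4, Kcnj6, Mbp and Fos. These genes were named after their values were seen. Beside a named oligo that passed, the other oligo of Grm3, Grm7, Cnr1, Cort, Ntrk3 and Tgfb1 did not pass, with differences from -0.61 to 0.18.

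**Figure D4:**
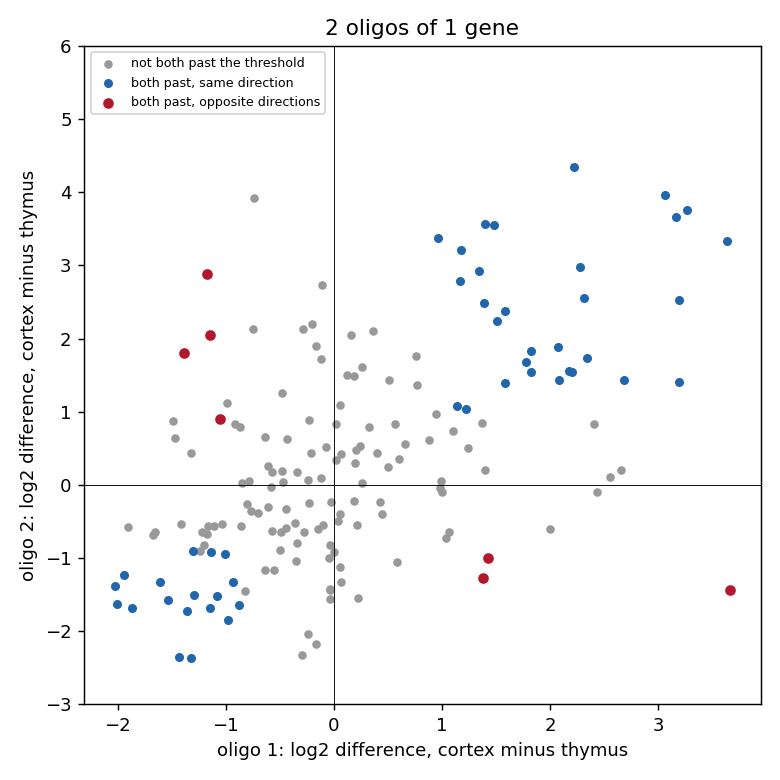
Log2 difference, cortex minus thymus, of the first oligo (x axis) and the second (y axis) of 173 sequence entries, with a point per entry. The 48 entries with both oligos past the threshold in 1 direction are blue, and the 7 in opposite directions are red.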

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

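The tests on second oligos, unscaled values, dim thymus spots and the value table were chosen after related results were seen. Control spots outside the comparison gave signal above the blank spots. The mean net signal of a control printed as XCP2-S1 was above the highest unflagged blank spot on 4 of 6 arrays, at 1913 and 1908 on cortex 1 and 2 and 2819 and 1898 on thymus 1 and 2. One oligo of a control printed only by a sequence accession was above the highest blank on 5 of the 5 arrays with an unflagged spot, from 1396 to 4254. The sources used here do not say whether RNA for these controls was added.

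About as many probes were called higher in thymus, 110, as in cortex, 113. Of the 73 thymus-higher oligos with a tested second oligo, 79.5% had that oligo also below 0. The upper end of the 95% range with shuffled partners was 60.3%. The shuffled partners included those of cortex-higher oligos, so the comparison cannot decide whether unspecific signal of single oligos gives these calls. Scaling stays open: only 9 of the 110 had every unscaled thymus value above every unscaled cortex value, so most of these calls may come from scaling a dimmer set of arrays to a brighter one. Lifting of dim spots could not be settled, since 75 of the 110 were above background on all 3 thymus arrays, between a share under 0.5 that it predicts and one over 0.75 that it forbids. A difference between the tissues is open as well.

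The cortex 3 column of the deposited value table was 3.07 times the thymus 1 column at all 20 probes, from 3.070 to 3.074. A thymus array in the cortex 3 scanner file is argued against, since that file correlated with the cortex arrays at 0.916 or more and with the thymus arrays at 0.628 or less. The column may have been filled from thymus 1: 20 of its 20 values were within 1% of 1 multiple of the thymus 1 scanner values. No biological explanation was tested.

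Both oligos passed in opposite directions at 7 of 173 sequence entries. A saturated or dim oligo could be involved at 3 of the 7 (Prlr, Mbp and Fos), between the limits set beforehand, and does not decide the other 4. At Mbp, whose locus also makes the longer Golli transcripts known from thymus, the oligos differed by 3.66, saturated on 2 of 3 cortex arrays, and -1.44; whether they target different transcripts was not tested, since oligo sequences were not used here.

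Of the 10 splits of the 6 arrays into groups of 3, the real one gave 223 calls and the highest of the others 0 in limma (12 at an unadjusted p under 0.05, against 246 in the real split); it was the 1 split with as many. For gene lists the real split gave 2 and the highest other 1, a count that several of the other splits reached. Each of the other splits mixes the tissues in both groups. A tissue difference then widens the spread within groups, which makes calls of single probes there less likely. With 10 splits no share under 0.05 is possible.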

How the results depend on the processing

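The alternatives that leave out the coarse-grid arrays, use the authors' factors or leave the cortex 3 column out of the value table, and those for replicate agreement, were chosen after seeing the data. Against 223 calls (113 higher in cortex and 110 in thymus), counts within 1.5 times came from the other background, offset, scaling, dim-filter, spot, flag, block and eBayes settings not named here. The exceptions were no scaling (117, with 117 and 0), control-gene centring (36 in thymus), all 6 arrays above background (81, with 18 and 63, of 186 tested), treat against a fold of 1.5 (109, with 72 and 37), no coarse-grid arrays (110, with 44 and 66) and the authors' factors without cortex 3 (121, with 66 and 55, against 139, with 58 and 81, without cortex 3 alone). Leaving out single arrays gave 111 to 219 calls, 46 to 115 in cortex and 65 to 104 in thymus; fewer probes were tested there. Of the cortex-higher calls, 104 kept their call and direction under every scaling and without any, against 0 of the thymus-higher calls, 35 of which kept it with control-gene centring. The value table of 20 probes was not tested with its cortex 3 column, a multiple of thymus 1. Without it the table gave 0 calls in limma (1 at an unadjusted p under 0.05). Of the 10 probes tested in both, 5 passed in the scanner values. At those 10 probes the differences had the same sign at 8, with Pearson's r = 0.940. The table holds scaled values of the same arrays, so this likeness was largely set beforehand. The table's only list of at least 3 probes, potassium channels, did not pass (0 lists). Against 2 lists past camera, 4 passed with an offset of 10, cyclic loess, control-gene centring, median of spots or flagged spots kept, 0 with an estimated correlation, 0 of the 14 lists still testable with all 6 arrays above background (neuron markers were not among them), 1 without the coarse-grid arrays, and 13 in fry; leaving out single arrays gave 1 to 3. The adrenergic and serotonin lists lay at the threshold. Arrb2 went from -1.01 to 0.048 without scaling, and an Rps4x oligo from 0.46 to -0.88 with scan setting as a block. Mean correlation was 0.902 in cortex and 0.768 in thymus without background correction, 0.884 and 0.740 with plain subtraction, and with single arrays left out 0.917 to 0.951 and 0.799 to 0.871. The difference in probes above background was 176 above the highest blank, 116 with 1 SD and 131 to 193 with single arrays left out. With the replicate block 210 probes passed. Same-numbered arrays deviated with correlations of 0.17, -0.09 and 0.01, and other pairs with -0.24 to 0.19. With 3 arrays per tissue these correlations constrain each other, so they cannot show whether arrays were processed in pairs. Except where given, the cause was not tested. Signal over background left 48 probes with only a bound.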

Other observations

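The tests in this part were chosen after the data were seen. Genes that the files class as calcium binding proteins, a class outside the fixed lists, moved in both directions. Of 11 tested probes, 8 were higher in cortex and 2 in thymus under quantile scaling. Both oligos of Calb1 (calbindin), Calb2 (calretinin) and Pcp4 were higher in cortex; Calb2 was at least 2.01-fold and 1.66-fold higher, and one Pcp4 oligo differed by 2.07 ± 0.38 log2 units (SE, n = 3 arrays per tissue; adjusted p = 0.000294, limma). Both oligos of Pvalb (parvalbumin), a marker of a class of inhibitory neurons, were higher by 1.22 ± 0.46 and 1.03 ± 0.41. Of 3 tested oligos of S100g, the small intestinal calbindin, 2 were higher in thymus, at -1.43 ± 0.38 and -1.04 ± 0.36, and 1 did not pass, at -0.35 ± 0.38. The class as a whole did not pass camera (adjusted p = 0.122 over 25 classes, and 0.359 with an estimated correlation).

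The printed class of development genes had 7 of 24 probes higher in thymus and 1 in cortex under quantile scaling (camera adjusted p = 0.153). Besides Pax5 and Otx1 these were Meis1, Dlx1, Dlx2, Pax8 and En2, at -0.91 to -1.47 log2 units. The other oligos of Dlx1 and Pax8 did not pass, at -0.56 ± 0.41 and 0.05 ± 0.42. Both oligos of the intermediate filament gene Vim were also higher in thymus under quantile scaling, at -1.68 ± 0.45 and -1.14 ± 0.38. Without scaling 0 thymus-higher calls were kept. Of these thymus-higher development and Vim probes, only Pax5 had every unscaled thymus value above every unscaled cortex value. Of the 9 thymus-higher probes whose unscaled values also separated, Scnn1b, Pax5 and Rpsa were brighter in thymus by 1.67, 1.59 and 1.53 log2 units without scaling. Others among the 9 were Scnn1a, Htr3b, Vipr2, Kcna5 and a probe printed as rsk1.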
